A study of Mus musculus with 4 samples.

How the data were processed

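RNA was sequenced from CD44+ CD4 T cells sorted as Thy1.1+ (IFNγ-producing) or Thy1.1− (non-producing) from spleen and lymph nodes of Rag1-deficient mice of the C57BL/6 strain with transfer colitis, 4 weeks after they received CD45RBhi CD25− CD4 T cells from IFNγ reporter donors. Each group had 2 libraries, numbered 2 and 3 in the labels, made from pools of 8 to 10 mice. The labels do not state that the pools of a group were separate mice, or that libraries with the same number came from the same mice. The p-values of single genes rest on the spread between only these libraries. Those of the set tests compare a list's genes with the other genes and do not measure the spread between libraries. The closing observations give the values of sex-linked genes that bear on whether a group's libraries came from the same cells.

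The values come from the authors' deposited table of their own comparison, with 1 row for each of 18674 genes. The first measure is a mean normalized count, a signal the authors averaged over all libraries after scaling them for depth, per the file headers. The second is a log2 fold change with its standard error (lfcSE), as deposited by the authors. The third is a score, the authors' Wald statistic, which equals the deposited log2 fold change divided by its standard error to within 1.17e-13. The deposited p-values and adjusted p-values follow from that statistic. The submitters' processing notes name DESeq2 and the build GRCm38. The aligner, the counting tool, the gene annotation and the DESeq2 version are not given in the sources used here.

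The deposited values were checked for how they were made. The adjusted p-values equal a Benjamini-Hochberg adjustment over the 15777 genes that have one, to within 2.22e-15. The other 2897 genes have a mean normalized count of at most 28.9 and no adjusted p, and the lowest mean in the table is 10.0. No header or label states that the deposited fold changes were shrunken toward 0, and this was inferred from the values. Their largest standard error is 0.298, below the 0.455 that counting noise alone gives at the lowest mean, and the standard error rises with the mean among genes without an adjusted p (Spearman correlation across genes 0.949; genes are not independent replicates). A zero-centred prior with a standard deviation of 0.596, estimated from the standard errors, was used to remove the shrinkage as an alternative. Where the standard error allows a smaller and a larger correction, the smaller was taken, which can understate genes of low mean. It made the fold changes of changed genes larger by a median factor of 1.07, and changes no p. Fold changes printed are as deposited unless said otherwise, and understate the change of low or variable genes. A fold is 2 to the power of the deposited log2 fold change.

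The header does not name the direction of the fold changes. Positive values were read as higher in producing cells, because Ifng, on which the cells were sorted, is positive. Were that reading wrong, every direction would turn.

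Depth per library is unknown, because the deposited table holds no values per library. The authors' standard error stands for the precision of each value, with a median of 0.295 at means of 30 to 100 and 0.119 at means of 1000 to 100000. Above a mean of 1000 it corresponds to a median coefficient of variation between libraries of 8.39%.

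The design written before the data were examined assumed RPKM values per library and a limma fit on log2(RPKM + 1). The deposited table holds no such columns, so that fit could not be made, nor the comparison of libraries with each other. The authors' calls at an adjusted p under 0.05 were counted in its place. The gene lists fixed before the data were examined were tested with cameraPR of limma 3.58.1 (R 4.3.3) on the deposited Wald statistic. The preset correlation between genes was 0.01, the background was the 15777 genes with an adjusted p, and Benjamini-Hochberg adjustment ran over 34 lists. The lists cover helper T cell subsets, cytotoxic, progenitor and effector genes, inhibitory receptors, stimulation, trafficking, interferon responses, cell cycle, metabolism, sialylation, apoptosis, stress, mitochondrial mRNAs and markers of other cell types. Counts adjusted over the list alone apply Benjamini-Hochberg to the deposited p-values of a list's members. On simulated statistics for 15777 genes the set test called 100% of 500 shifted lists of 20 genes in the right direction, and 2.8% of unchanged lists at an unadjusted p under 0.05. The simulated genes were independent of each other, and every member of a shifted list moved by the same large amount. The simulation therefore does not show how the test behaves for correlated genes or small shifts. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 did the rest.

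Genes were named by a rule set before the data were examined. It takes Ifng and Thy1, the 12 largest changes in each direction among called genes with established symbols, 24 genes chosen in advance, and up to 4 examples per list. For lists of other cell types it takes the 2 most abundant members, and other members that passed were named beside them where a list has few. The rule also asked for groups that do not overlap and for a minimum RPKM, which could not be applied without values per library. Some genes the rule takes are not reported here. Coordinates are from the GENCODE M21 annotation of GRCm38, matched by symbol for 17400 of the 18674 genes (93.2%). Genes that share reads with near-identical copies, such as the histone, Gbp, Serpina3 and killer receptor families and the paired genes Hspa1a with Hspa1b, are uncertain to the extent that the counting split them.

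Alternatives changed the threshold, the filter on low values, the centring of fold changes, the shrinkage, and the ranking value, preset correlation and form of the set test. Settings chosen before the data were examined that need values per library were not run.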

Results

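Gene expression was measured by RNA sequencing in CD4 T cells of mice with transfer colitis, an intestinal inflammation that develops when naive CD4 T cells are given to hosts without lymphocytes of their own. The donor cells carried a reporter that puts Thy1.1 on the surface of cells expressing Ifng, the gene of interferon gamma (IFNγ). At 4 weeks after transfer into Rag1-deficient hosts, antigen-experienced (CD44+) cells from spleen and lymph nodes were sorted into IFNγ-producing (Thy1.1+) and non-producing (Thy1.1−) cells, with 8 to 10 colitic mice pooled. There were 2 libraries of each kind. The data analysed here are the authors' deposited table of this comparison, which lists 18674 genes and holds no values per library. Each gene has a mean normalized count over all libraries, a log2 fold change with its standard error (SE) and, for most genes, an adjusted p. The means of the authors' deposited table sum to 6.16e+07 normalized counts. The mitochondrial ribosomal RNA mt-Rnr2 holds 10.8% of that sum in the authors' deposited table, and the 5 most abundant genes hold 17.6%. The depth of each library is therefore unknown, and the precision of each value is that of the authors' SE, with a median of 0.159 over the 15777 genes that have an adjusted p.

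The comparison asks how CD4 T cells that make IFNγ during chronic intestinal inflammation differ in their transcripts from those that do not. IFNγ-producing cells had more transcripts of inflammatory chemokines, Th1 regulators and cytotoxic granule genes, and fewer of genes of naive, memory and follicular helper T cells, of the Th2 program and of MHC class II. Whether the class II transcripts came from the T cells or from other cells in the non-producing sort stays open. Whether other cells in that sort contributed to the remaining falls was not tested. The chemokine Ccl3 was 12.4-fold higher in producing cells in the authors' deposited table, and the lymph node homing receptor Ccr7 was 22.9-fold higher in non-producing cells. Tcf7, the transcription factor TCF1 of naive and stem-like T cells, was 5.72-fold higher in non-producing cells in the authors' deposited table, whereas the granule protease Gzmb was 3.52-fold higher in producing cells. In all, 2033 of 15777 genes (12.9%) had an adjusted p under 0.05 in the authors' deposited table, 942 of them higher and 1091 lower in producing cells. The submitters' processing notes name DESeq2 as the tool. Falls were the larger changes, with 80 genes lower by at least 2 on the log2 scale and 18 higher by as much in the authors' deposited table.

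**Figure D1:**
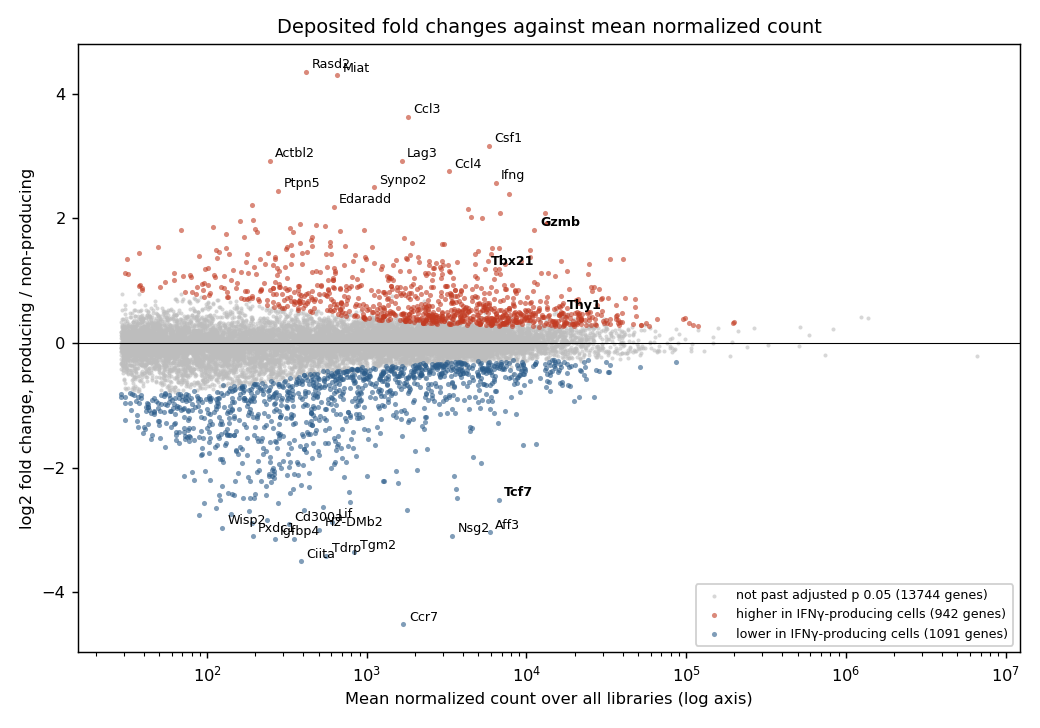
Each point is 1 of the 15777 genes with an adjusted p in the authors' deposited table, with its mean normalized count over all libraries on a log axis and its log2 fold change between producing and non-producing cells. Of the changed genes, 942 lie above the zero line and 1091 below it, from Rasd2 at 4.36 to Ccr7 at −4.52.

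The genes tied to the sort come first and are no finding. Ifng (chromosome 10, 118441046 to 118445892, GRCm38) had a log2 fold change of 2.57 ± 0.11 (SE) in the authors' deposited table. Thy1 (chromosome 9, 44043384 to 44048579) had 0.48 ± 0.10 (SE) in the authors' deposited table, where its reads can come from the endogenous gene as well as the reporter. The header of the authors' deposited table does not name the direction of its fold changes, and positive values are read here as higher in producing cells because Ifng is positive, so Ifng cannot serve as a check of the labels.

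The largest named rises in the authors' deposited table were led by Rasd2, a small GTPase (4.36 ± 0.23 SE, adjusted p = 2.05e-75), and the long noncoding RNA Miat (4.30 ± 0.22 SE, adjusted p = 7.98e-85), both by DESeq2. Secreted factors followed in the authors' deposited table, with Ccl3 at 3.63 ± 0.17 (SE), the macrophage growth factor Csf1 at 3.17 ± 0.13 (SE) and Ccl4 at 2.76 ± 0.27 (SE). The inhibitory receptor Lag3 rose by 2.93 ± 0.16 (SE) on the log2 scale in the authors' deposited table, and further named rises were Actbl2 (2.93), Synpo2 (2.50), Ptpn5 (2.44) and Edaradd (2.18). Rasd2 lies on chromosome 8 (75213944 to 75224113), Miat on chromosome 5 (112213228 to 112229395), and Ccl3 and Ccl4 neighbour each other on chromosome 11 (83647844 to 83649355 and 83662584 to 83664683), all on GRCm38.

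The largest falls in the authors' deposited table were Ccr7 (−4.52 ± 0.17 SE, adjusted p = 8.34e-158 by DESeq2; chromosome 11, 99144196 to 99155077) and Ciita, the master activator of MHC class II transcription (−3.51 ± 0.25 SE, adjusted p = 1.40e-40 by DESeq2; chromosome 16, 10480059 to 10528418). Next in the authors' deposited table came Tdrp at −3.42 ± 0.18 (SE), the transglutaminase Tgm2 at −3.36 ± 0.18 (SE), Igfbp4 at −3.14 ± 0.24 (SE) and Nsg2 at −3.09 ± 0.13 (SE). Pxdc1 (−3.09), the nuclear factor Aff3 (−3.04), the MHC class II chaperone gene H2-DMb2 (−3.0), Wisp2 (−2.97), the inhibitory receptor Cd300a (−2.91) and the cytokine Lif (−2.87) completed the 12 largest named falls in the authors' deposited table.

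Th1 genes rose as a group. Of 19 tested members, 11 rose, 1 fell and 7 did not pass in the authors' deposited table. The Th1 list had 13 higher and 1 lower adjusted over the list alone, a median of 0.44 and an adjusted p of 1.31e-18 by limma's cameraPR. Among the members that rose, the authors' deposited table gives the tissue homing receptor Cxcr6 at 1.93 ± 0.10 (SE) and the interleukin 12 receptor chain Il12rb2 at 1.32 ± 0.13 (SE). Tbx21, which encodes the Th1 lineage factor T-bet, was at 1.19 ± 0.12 (SE) in the authors' deposited table. The member that fell was Ifngr2, the signalling chain of the IFNγ receptor, at −2.44 ± 0.26 (SE) in the authors' deposited table. Ifngr1, its ligand-binding partner, was at 0.44 ± 0.11 (SE) in the authors' deposited table. Cxcr3, a Th1 chemokine receptor, had −0.15 ± 0.10 (SE) in the authors' deposited table and did not pass (adjusted p = 0.462 by DESeq2).

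Effector cytokines and chemokines other than Ifng rose more often than they fell. Of 20 tested members, 13 rose, 4 fell and 3 did not pass in the authors' deposited table. The effector cytokine list had 13 higher and 6 lower adjusted over the list alone, a median of 0.74 and an adjusted p of 2.70e-16 by limma's cameraPR. The chemokine Ccl5 at 2.09 ± 0.10 (SE) and the anti-inflammatory cytokine Il10 at 1.63 ± 0.20 (SE) rose in the authors' deposited table. Tnf at 0.92 ± 0.11 (SE) and Csf2 at 0.57 ± 0.19 (SE) rose as well in the authors' deposited table. The T cell growth factor Il2 fell, at −0.88 ± 0.20 (SE) in the authors' deposited table, as did Tnfsf8 (−1.64), Tnfsf11 (−0.91) and Osm (−0.67). A rank-based form of the set test did not call this list (limma's cameraPR, adjusted p = 0.0502).

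The list of cytotoxic granule and killer receptor genes was higher in producing cells. Of 22 tested members, 15 rose, 1 fell and 6 did not pass in the authors' deposited table. The cytotoxic list had 16 higher and 1 lower adjusted over the list alone, a median of 0.76 and an adjusted p of 7.37e-30 by limma's cameraPR. Nkg7 at 1.92 ± 0.11 (SE), Gzmb at 1.82 ± 0.10 (SE), perforin (Prf1) at 1.68 ± 0.13 (SE) and the death ligand Fasl at 1.53 ± 0.15 (SE) are examples from the authors' deposited table. The lysosomal protein gene Lamp1 fell, at −0.52 ± 0.10 (SE) in the authors' deposited table. Of the list of CD8 and gamma-delta T cell genes, 2 were higher alongside. They were Cd8a at 1.14 ± 0.29 (SE), or 1.79 without shrinkage, and the receptor gene Tcrg-C2 at 1.57 ± 0.24 (SE) in the authors' deposited table. Cd8b1, the other CD8 chain, was not higher, at −0.16 ± 0.27 (SE) in the authors' deposited table (adjusted p = 0.873 by DESeq2). The gamma-delta gene Trdc, also on that list, is absent from the authors' deposited table. Whether such cells were in the sort was not tested. Effector differentiation genes also rose. In the authors' deposited table, 11 of 22 rose, 1 fell and 10 did not pass. The effector differentiation list had 12 higher and 1 lower adjusted over the list alone and an adjusted p of 2.24e-09 by limma's cameraPR. Klrg1, a receptor of terminal effector cells, was at 1.59 ± 0.16 (SE) in the authors' deposited table. The transcription factors Zeb2 and Prdm1 were at 1.31 ± 0.27 (SE) and 1.14 ± 0.13 (SE) in the authors' deposited table.

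Genes of naive, central memory and stem-like T cells fell as a group. Of 28 tested members, 2 rose, 19 fell and 7 did not pass in the authors' deposited table. The progenitor list had 3 higher and 20 lower adjusted over the list alone, a median of −0.87 and an adjusted p of 8.07e-49 by limma's cameraPR. Beside Ccr7 and Igfbp4, the authors' deposited table gives Id3 at −2.64 ± 0.18 (SE), Tcf7 at −2.52 ± 0.11 (SE) and Lef1 at −0.65 ± 0.16 (SE). The interleukin 7 receptor Il7r at −0.58 ± 0.11 (SE) and the survival factor Bcl2 at −0.70 ± 0.10 (SE) fell too in the authors' deposited table. The members that rose in the authors' deposited table were Il2rb (0.51), a chain of the receptors for interleukin 2 and its relatives, and the transcription factor Eomes (0.60).

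Follicular helper genes fell as a group. Of 17 tested members, 2 rose, 13 fell and 2 did not pass in the authors' deposited table. The follicular helper list had 3 higher and 13 lower adjusted over the list alone, a median of −1.13 and an adjusted p of 2.66e-21 by limma's cameraPR. The follicle homing receptor Cxcr5 was at −2.04 ± 0.15 (SE) and Slamf6 at −1.92 ± 0.11 (SE) in the authors' deposited table. Lists share members, so their results are not independent. Cxcr5 is also on the progenitor list, and the follicular helper genes Btla and Cd200 are also on the inhibitory receptor list. The lineage factor Bcl6 was at −0.08 ± 0.13 (SE) in the authors' deposited table and did not pass. Pdcd1 (0.84) and Il21 (0.91) were the members that rose in the authors' deposited table. Th2 and Th9 genes fell as well, 8 of 12 in the authors' deposited table, with 1 higher and 3 not past. The Th2 list had 1 higher and 10 lower adjusted over the list alone, a median of −1.37 and an adjusted p of 4.00e-18 by limma's cameraPR. Il9r at −2.68 ± 0.13 (SE), Il13 at −2.34 ± 0.23 (SE) and the lineage factor Gata3 at −1.05 ± 0.11 (SE) fell in the authors' deposited table. Il1rl1, the interleukin 33 receptor, rose at 1.25 ± 0.12 (SE) in the authors' deposited table. Dendritic cell and MHC class II genes moved in the same direction as these lists, with a median of −0.99 over 11 members in the authors' deposited table.

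**Figure D2:**
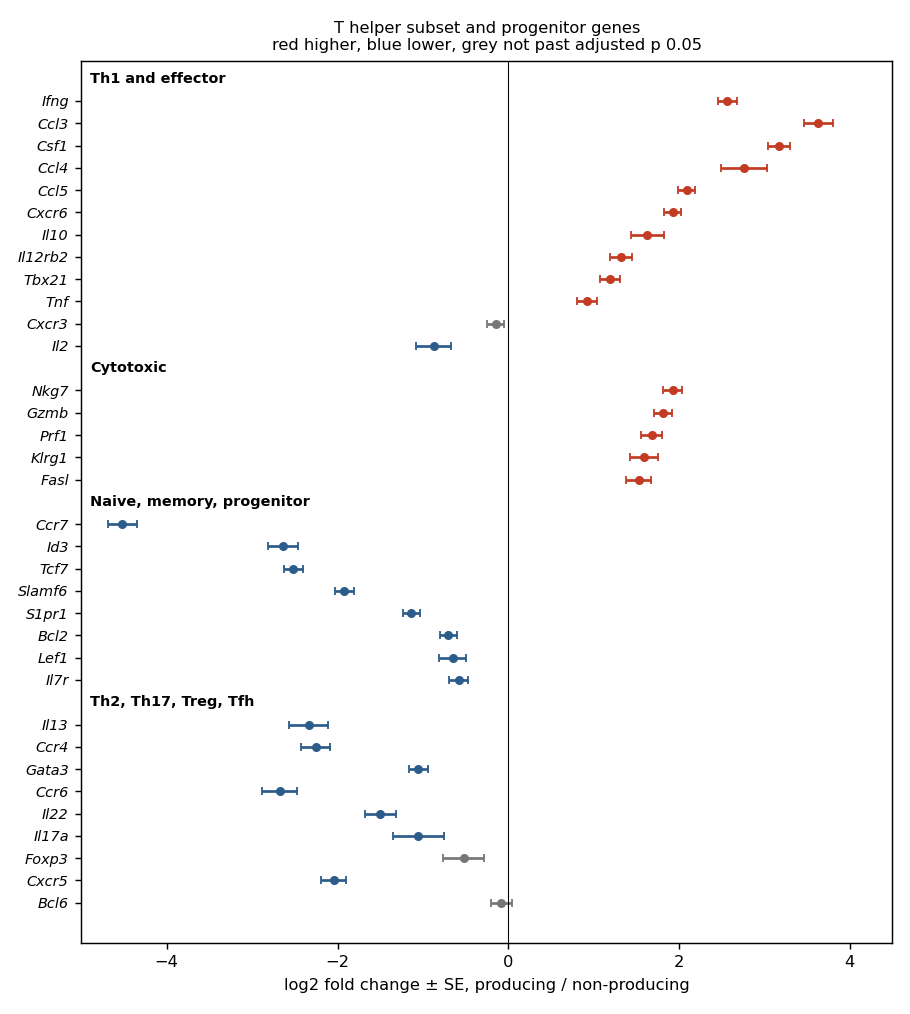
Log2 fold changes with the authors' SE as error bars are drawn for genes of T helper subsets, cytotoxic genes and progenitor genes from the authors' deposited table, with red for higher, blue for lower and grey for genes that did not pass. The genes drawn are a selection of the lists' members, in which the cytotoxic genes lie between 1.53 and 1.92 and the progenitor genes between −4.52 and −0.58.

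Th17 genes did not move as a group. Of 19 tested members, 5 rose, 6 fell and 8 did not pass in the authors' deposited table. The Th17 list had 5 higher and 6 lower adjusted over the list alone and an adjusted p of 0.175 by limma's cameraPR. The receptor Ccr6 at −2.68 ± 0.20 (SE) and the cytokine Il22 at −1.50 ± 0.18 (SE) fell in the authors' deposited table. Il17a at −1.06 ± 0.30 (SE), or −2.07 with the shrinkage of its fold change removed, was lower too in the authors' deposited table. Il21, the leukotriene receptor Ltb4r1 (0.93) and the transcription factor Maf (0.64) were among the members that rose in the authors' deposited table. Regulatory T cell genes split as well, with 4 higher, 5 lower and 9 not past of 18 in the authors' deposited table. The regulatory T cell list had the same counts adjusted over the list alone and an adjusted p of 0.704 by limma's cameraPR. Foxp3, the lineage factor, was at −0.52 ± 0.24 (SE) in the authors' deposited table and did not pass (adjusted p = 0.153 by DESeq2). Nrp1 fell at −1.69 ± 0.18 (SE) in the authors' deposited table, and Il10 and Tnfrsf9 (1.31) were among those that rose.

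Inhibitory receptors and exhaustion regulators moved in both directions. Of 17 tested members, 7 rose, 4 fell and 6 did not pass in the authors' deposited table. The inhibitory receptor list had 7 higher and 4 lower adjusted over the list alone and an adjusted p of 0.0342 by limma's cameraPR. The test and the list's mean of 0.21 point upward, whereas its median in the authors' deposited table was −0.14. At a preset correlation of 0.05 the call was lost (limma's cameraPR, adjusted p = 0.107). Beside Lag3, the ectonucleotidase gene Entpd1 rose at 1.28 ± 0.14 (SE) in the authors' deposited table. Btla at −1.13 ± 0.13 (SE) and Cd200 at −1.10 ± 0.19 (SE) fell in the authors' deposited table. Genes of recent T cell receptor stimulation had 4 higher, 2 lower and 14 not past of 20 in the authors' deposited table. The stimulation list had 4 higher and 3 lower adjusted over the list alone and an adjusted p of 0.637 by limma's cameraPR. Egr2 was at 1.18 ± 0.12 (SE) and Cd83 at −1.31 ± 0.30 (SE), or −2.42 without shrinkage, in the authors' deposited table. Trafficking receptors and integrins had 7 higher, 5 lower and 9 not past of 21 in the authors' deposited table, among them the integrin chain Itga1 at 1.42 ± 0.13 (SE). The trafficking list had the same counts adjusted over the list alone and an adjusted p of 0.592 by limma's cameraPR.

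IFNγ-induced genes rose as a group. Of 28 tested members, 16 rose, 2 fell and 10 did not pass in the authors' deposited table. The IFNγ-induced list had 19 higher and 4 lower adjusted over the list alone, a median of 0.35 and an adjusted p of 1.74e-06 by limma's cameraPR. The guanylate-binding proteins Gbp6 at 0.98 ± 0.11 (SE) and Gbp3 at 0.87 ± 0.11 (SE) rose in the authors' deposited table. Ciita and Tgtp1, the latter at −1.02 ± 0.29 (SE) or −1.76 without shrinkage, were the members that fell in the authors' deposited table. Ranked by log2 fold change in place of the test statistic, the list was not called (limma's cameraPR, adjusted p = 0.0658). Type I interferon genes had 3 higher, 6 lower and 16 not past of 25 in the authors' deposited table. The type I interferon list had 5 higher and 9 lower adjusted over the list alone and an adjusted p of 0.459 by limma's cameraPR. Mx1 was at 1.15 ± 0.15 (SE) and Oasl2 at −1.69 ± 0.24 (SE) in the authors' deposited table.

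Glycolysis genes rose as a group. Of 25 tested members, 12 rose, 2 fell and 11 did not pass in the authors' deposited table. The glycolysis list had 14 higher and 2 lower adjusted over the list alone, a median of 0.29 and an adjusted p of 0.000266 by limma's cameraPR. The lactate transporter Slc16a3 at 0.89 ± 0.13 (SE) and the glucose transporter Slc2a3 at 0.83 ± 0.12 (SE) led them in the authors' deposited table. Nuclear genes of the respiratory chain and ATP synthase shifted slightly upward, with positive values in 56 of 59, of which 3 passed in the authors' deposited table, and 0 lower. The respiratory chain list had 2 higher and 0 lower adjusted over the list alone, a median of 0.17 and an adjusted p of 0.000335 by limma's cameraPR. Cox5a was at 0.50 ± 0.13 (SE) in the authors' deposited table. Cell cycle genes showed a like shift, with 5 higher and 0 lower of 41 in the authors' deposited table. The cell cycle list had the same counts adjusted over the list alone, a median of 0.24 and an adjusted p of 0.000935 by limma's cameraPR. Prc1 rose at 0.54 ± 0.15 (SE) in the authors' deposited table, and the proliferation marker Mki67 was at 0.14 ± 0.25 (SE) and did not pass. Genes of apoptosis and survival had 8 higher, 1 lower (Bcl2) and 15 not past of 24 in the authors' deposited table. The apoptosis list had 9 higher and 1 lower adjusted over the list alone and an adjusted p of 0.000562 by limma's cameraPR. The death-promoting Bcl2l11 rose at 1.04 ± 0.12 (SE) in the authors' deposited table.

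Other metabolic lists were not called. Fatty acid oxidation had 4 genes higher, 3 lower and 22 not past of 29 in the authors' deposited table. The fatty acid list had 5 higher and 5 lower adjusted over the list alone and an adjusted p of 0.427 by limma's cameraPR. Ech1 was at 0.80 ± 0.10 (SE), Acsl1 at −0.48 ± 0.14 (SE) and the transporter Cpt1a at −0.16 ± 0.13 (SE), not past the threshold, in the authors' deposited table. Of 23 tricarboxylic acid cycle genes, Idh2 fell at −0.91 ± 0.15 (SE) in the authors' deposited table and 0 rose. Of 23 genes of mitochondrial maintenance, Polg (−0.49) and Polg2 (−0.41) fell in the authors' deposited table and 0 rose. Of 24 cholesterol synthesis genes, 1 fell and 0 rose in the authors' deposited table. These lists had the same counts adjusted over the list alone and adjusted p of 0.711, 0.675 and 0.704 in that order by limma's cameraPR. Sialic acid genes split into 4 higher, 4 lower and 13 not past of 21 in the authors' deposited table. The sialic acid list had 5 higher and 6 lower adjusted over the list alone and an adjusted p of 0.675 by limma's cameraPR. St3gal3 rose at 1.30 ± 0.13 (SE) and St8sia6 fell at −1.53 ± 0.24 (SE) in the authors' deposited table. St6gal1 was at −1.36 ± 0.29 (SE) in the authors' deposited table, or −2.19 with the shrinkage removed.

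**Figure D3:**
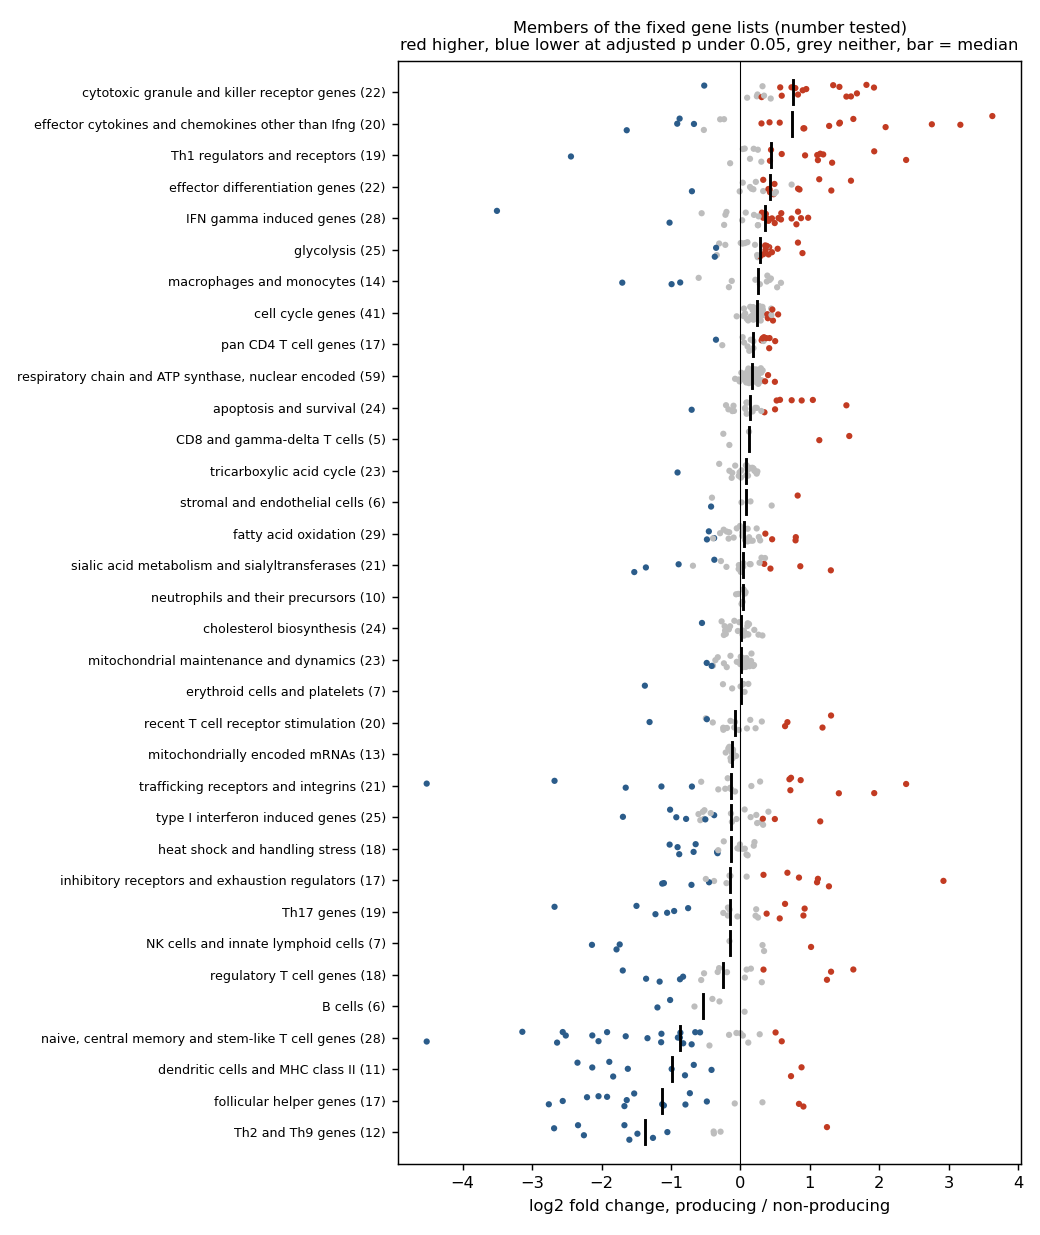
Each point is 1 tested member of a fixed gene list, placed by its log2 fold change in the authors' deposited table, with black bars at the list medians and the number of tested members in brackets. Medians run from −1.37 for Th2 and Th9 genes to 0.76 for cytotoxic genes.

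Genes that every CD4 T cell uses shifted slightly upward. Of 17 tested members, 7 rose, 1 fell and 9 did not pass in the authors' deposited table. The T cell identity list had 8 higher and 2 lower adjusted over the list alone, a median of 0.19 and an adjusted p of 0.00329 by limma's cameraPR. Cd3g was at 0.50 ± 0.09 (SE) and Cd28 at −0.35 ± 0.10 (SE) in the authors' deposited table. Ranked by log2 fold change the list was not called (limma's cameraPR, adjusted p = 0.0775). Heat shock and handling stress genes fell in 7 of 18 cases with 0 higher in the authors' deposited table, Hspa1a at −1.02 ± 0.14 (SE) and Fos at −0.64 ± 0.11 (SE) among them. The heat shock list had the same counts adjusted over the list alone and an adjusted p of 0.00271 by limma's cameraPR. Its call was lost by log2 fold change (adjusted p = 0.0503) and by ranks (adjusted p = 0.0502), both with limma's cameraPR. Of the 13 mitochondrially encoded mRNAs 0 passed in the authors' deposited table, also adjusted over the list alone. mt-Co1 was at −0.21 ± 0.15 (SE) and mt-Co3 at −0.15 ± 0.12 (SE) in the authors' deposited table. The mitochondrial mRNA list had an adjusted p of 0.297 by limma's cameraPR, or 0.00665 by ranks.

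Among markers of other cell types, dendritic cell and MHC class II genes changed most, with 9 of 11 lower and 2 higher in the authors' deposited table. The dendritic cell list had the same counts adjusted over the list alone and an adjusted p of 2.73e-06 by limma's cameraPR. Cd74, the class II invariant chain, was at −1.62 ± 0.30 (SE) and H2-Eb1 at −1.83 ± 0.30 (SE) in the authors' deposited table, with mean normalized counts of 11490 and 4630. Without shrinkage these fold changes were −2.86 and −3.63. Across genes with means of 1000 to 100000 the median SE was 0.119, so both genes varied more than most between libraries of a group. Natural killer and innate lymphoid genes had 3 lower, 1 higher and 3 not past of 7 in the authors' deposited table. The natural killer list had the same counts adjusted over the list alone and an adjusted p of 0.0396 by limma's cameraPR. Its call was lost without the filter on low values (adjusted p = 0.142), at a preset correlation of 0.05 (0.0752) and by ranks (0.69), all with limma's cameraPR. Gzma at 0.32 ± 0.30 (SE), or 0.57 without shrinkage, and Klrb1c at 0.34 ± 0.19 (SE), its most abundant members, did not pass in the authors' deposited table. B cell genes had 2 lower and 0 higher of 6 in the authors' deposited table, Ighm at −1.20 ± 0.29 (SE) and Cd22 at −1.01 ± 0.29 (SE), or −1.88 and −1.71 without shrinkage. The B cell list had 3 lower and 0 higher adjusted over the list alone and an adjusted p of 0.0729 by limma's cameraPR, or 0.00362 by log2 fold change and 0.021 by ranks.

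Macrophage and monocyte genes had 3 lower and 0 higher of 14 in the authors' deposited table, with Lyz2 at 0.39 ± 0.16 (SE), which did not pass, and Mpeg1 at −0.99 ± 0.29 (SE), or −1.71 without shrinkage. Emr1, a macrophage surface receptor, at −1.70 ± 0.24 (SE) and Itgam at −0.87 ± 0.22 (SE) were the other members that fell in the authors' deposited table. The macrophage list had 4 lower and 2 higher adjusted over the list alone and an adjusted p of 0.704 by limma's cameraPR. Its median was 0.25, with 8 members positive and 6 negative. Genes of CD8 and gamma-delta T cells had 2 higher and 0 lower of 5 in the authors' deposited table, Tcrg-C2 and Cd8a, while Cd8b1 and Cd163l1, the latter at −0.25 ± 0.19 (SE), were negative and did not pass. The CD8 list had the same counts adjusted over the list alone and an adjusted p of 0.152 by limma's cameraPR, or 0.0163 by log2 fold change. Of 10 neutrophil genes 0 passed in the authors' deposited table, with S100a9 at 0.04 ± 0.24 (SE) and S100a8 at 0.07 ± 0.23 (SE). Erythroid and platelet genes had 0 higher and 1 lower of 7 in the authors' deposited table, Car2 at −1.38 ± 0.29 (SE) or −2.26 without shrinkage, with the globins Hbb-bs at 0.05 ± 0.24 (SE) and Hba-a1 at 0.06 ± 0.27 (SE). Stromal and endothelial genes had 1 higher and 1 lower of 6 in the authors' deposited table, Igfbp7 at 0.83 ± 0.22 (SE) and Pecam1 at −0.42 ± 0.11 (SE). The last 3 lists had the same counts adjusted over the list alone and adjusted p of 0.901, 0.589 and 0.921 by limma's cameraPR.

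**Figure D4:**
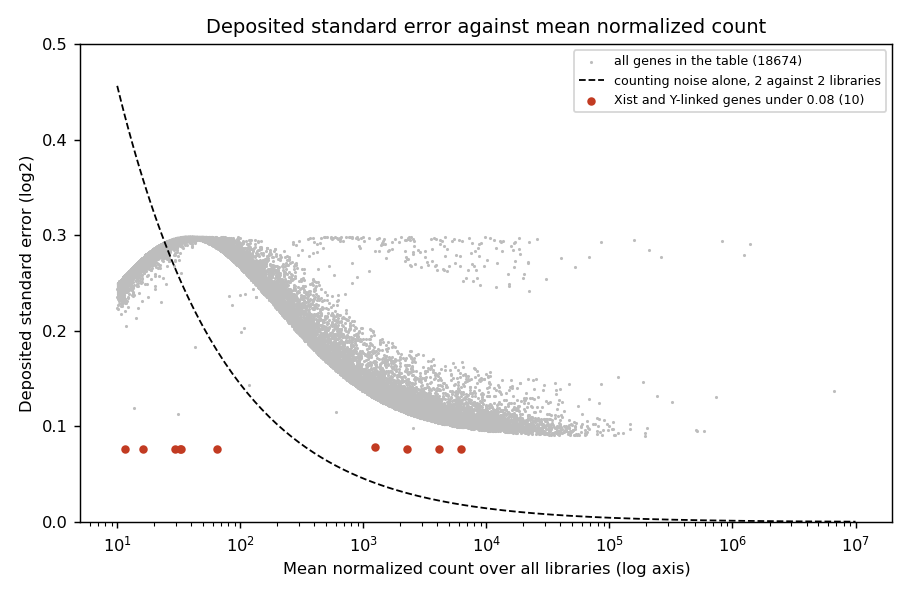
The authors' SE of the log2 fold change is drawn against the mean normalized count on a log axis for each gene of the authors' deposited table, with the SE that counting noise alone would give as a dashed line. The SE peaks at 0.298, and 10 genes in red, Xist and 9 genes of the Y chromosome, lie under 0.08.

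The gene p-values behind these counts rest on the spread between the 2 pooled libraries of each group. No set test with an estimated correlation could be run without values per library, so the list calls rest on the preset correlation of 0.01.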

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

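The adjustment over all genes was chosen before the result was seen. Of the 2897 genes without an adjusted p in the authors' deposited table, which the counts of changed genes leave out, 14 pass 0.05 when the deposited p-values are adjusted over all 18674 genes (Benjamini-Hochberg). The same adjustment ends 67 of the 2033 calls, so that the total falls to 1980. Of the 14 genes, 10 are lower and 4 higher in producing cells, and 57 of the 2897 have an unadjusted p under 0.05. The gene with the smallest p is Cbfa2t3, a transcriptional corepressor, at −1.05 ± 0.27 (SE) in the authors' deposited table with a mean normalized count of 21.3. Tlr3, at −0.91 ± 0.28 (SE), and Hes1, a target of Notch signalling, at −0.80 ± 0.28 (SE) in the authors' deposited table, were also lower. The smaller correction for shrinkage gives −1.40 and −1.23. It is likely to understate both falls, since the SE rises with the mean among genes this low. Cbfa2t3, Tlr3 and Hes1 were chosen here after their values were seen. No explanation was tested.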

How the results depend on the processing

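Settings that need values per library were not run: pseudocounts, RPKM filters, quantile and TMM scaling, eBayes settings, leaving out a replicate, an estimated correlation, fry, count models and likeness of libraries. No paired analysis was possible because the deposited table holds one comparison and no values per library. The limits on precision are the pooled libraries, 2 per group, and an unknown depth. Centring of fold changes, removed shrinkage, a mean of at least 100, a preset correlation of 0.05, ranking by log2 fold change and rank-based tests were chosen after seeing the data. No called list turned direction. The 3 settings for single genes were followed for 48, which are Ifng, Thy1, the largest changes and those chosen in advance. All 48 kept their direction and side of the threshold, which these settings could hardly have changed. Removing the shrinkage alters neither, the adjustment over all genes cannot turn a direction, and centring moved each value by only 0.011. Without shrinkage, 3 of the 48 moved by over 1.5 times, among them Il17a to −2.07 and St6gal1 to −2.19. Other genes named were not followed, and several moved as much without shrinkage. Asking also for a log2 fold change of at least 1 left 588 changed genes, 185 higher and 403 lower, fewer by construction. Other settings gave 1477 to 2479 changed genes against 2033, and centring on the median of 0.011 gave 887 higher and 1120 lower.

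Set tests are limma's cameraPR with adjusted p. Of 34 lists, ranking by log2 fold change ended the calls of T cell identity (0.0775), inhibitory receptors (0.0525), IFNγ-induced (0.0658) and heat shock genes (0.0503), and added B cell (0.00362) and CD8 and gamma-delta genes (0.0163). Rank-based tests ended effector cytokines (0.0502), inhibitory receptors (0.941), heat shock (0.0502) and natural killer genes (0.69), and added mitochondrial mRNAs (0.00665) and B cell genes (0.021). A preset correlation of 0.05 ended inhibitory receptors (0.107) and natural killer genes (0.0752), and no filter on low values ended natural killer genes (0.142). Over all alternatives the adjusted p ran from 0.000701 to 0.0775 for T cell identity, 7.03e-19 to 0.0502 for effector cytokines, 0.0192 to 0.941 for inhibitory receptors, 1.81e-07 to 0.0658 for IFNγ-induced genes and 0.00114 to 0.0503 for heat shock. It ran from 0.00143 to 0.69 for natural killer, 0.00362 to 0.131 for B cell, 0.0163 to 0.589 for CD8 and gamma-delta genes and 0.00665 to 0.508 for mitochondrial mRNAs. Among lists that no setting called, rank-based tests turned the direction of stimulation (0.69), trafficking (0.759) and macrophage genes (0.759), and ranking by log2 fold change that of trafficking (0.323) and sialic acid genes (0.798). The cause was not tested. These and the rest of the 25 other lists stayed on their side of the threshold under these 4 settings.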

Other observations

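Gene families that the fixed lists do not hold were grouped by symbol after the values were seen, and 13 were tested with limma's cameraPR, adjusted over the 13. Their p-values describe these groups and are no test of a pattern set in advance. All 8 tested Gimap genes, GTPases of lymphocytes, rose in producing cells in the authors' deposited table, with a median of 0.35 (adjusted p = 3.21e-06 by limma's cameraPR) and Gimap7 highest at 1.04 ± 0.14 (SE). Serpins, protease inhibitors of which some protect cells from their own granule proteases, rose in 9 of 19 cases and fell in 2 in the authors' deposited table (limma's cameraPR, adjusted p = 3.16e-09). Serpina3f was at 2.02 ± 0.14 (SE), Serpinb9b at 1.71 ± 0.28 (SE) and Serpina3g at 1.31 ± 0.11 (SE) in the authors' deposited table. Histone genes rose in 28 of 65 cases and fell in 1, Hist1h4m at −1.57 ± 0.27 (SE), in the authors' deposited table (median 0.42; limma's cameraPR, adjusted p = 4.55e-08). Of 43 proteasome genes 7 rose and 0 fell in the authors' deposited table (limma's cameraPR, adjusted p = 4.37e-05), with the activator subunit Psme2 at 0.51 ± 0.11 (SE).

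Toll-like receptors were lower in 5 of 9 cases and higher in 0 in the authors' deposited table (median −0.94; limma's cameraPR, adjusted p = 1.41e-05), among them Tlr1 at −1.35 ± 0.16 (SE). Most dendritic cell genes and some macrophage and B cell genes were lower too. Whether other cells in the non-producing sort account for the fall of Toll-like receptors was not tested. Cytosolic ribosomal protein genes shifted slightly downward, with 3 of 72 lower, 0 higher and a median of −0.11 in the authors' deposited table (limma's cameraPR, adjusted p = 0.00348). Ms4a genes rose in 4 of 7 cases (limma's cameraPR, adjusted p = 0.00117), and killer lectin receptors had 6 higher and 2 lower of 16 in the authors' deposited table (limma's cameraPR, adjusted p = 0.0637). Chemokine receptors (adjusted p = 0.275), integrins (1), genes named Zfp (0.314) and solute carriers (0.47) were not called as families by limma's cameraPR.

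For the patterns below, the innate lymphoid cell test and the test of GC content and transcript length were set before their results were seen, and the tests of B cells, macrophages, dendritic cells, T cell share and sex were chosen after. MHC class II genes of the H2 complex were lower in producing cells in 9 of 9 cases in the authors' deposited table. This family too was grouped after falls of some of its members had been seen, so the p of its set test is left out. Dendritic cells in the non-producing sort stay open: 8 dendritic genes outside class II had a median of −0.54, with 5 lower and 2, Xcr1 and Ccr9, higher in the authors' deposited table, but these genes belong to the pattern itself and decide nothing. B cells and macrophages stay open too: the mean of Cd79a was 0.786% of that of Cd74 and Lyz2 was at 0.39, with a lower confidence bound of 0.077, but Ighm (−1.20), Cd22 (−1.01), Emr1 (−1.70) and Mpeg1 (−0.99) were lower in the authors' deposited table. The macrophage list as a whole had a median of 0.25, with 8 members positive and 6 negative. Innate lymphoid cells that carry CD4 and class II stay open as well, since their 6 measured genes had a median of −0.24 with 1 called lower. Expression of class II by the T cells themselves was not tested.

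The fall of progenitor genes and the rise of cytotoxic genes were set against technical trends. With the trend over GC content and transcript length removed, both lists were still called by limma's cameraPR (adjusted p = 6.87e-48 and 3.13e-28). On the same genes without the removal, limma's cameraPR gave adjusted p of 3.89e-48 and 2.57e-29. The Wald statistic followed GC content and length only weakly (Spearman correlation across genes −0.031 and −0.121). Such trends were too weak to account for either list, and the test could hardly have come out otherwise. Fewer T cells in the non-producing sort could raise T cell genes in producing cells, and a first test was undecided: the T cell identity list had a median of 0.188, and its upper quartile of 0.339 overlapped the lower quartile of 0.324 of the cytotoxic list. A second test, picked only after the first came out undecided, set the highest T cell identity value, 0.501 for Cd3g, below the cytotoxic median of 0.76. Its outcome was known when it was picked. A shortage of T cells would raise all T cell genes by about the same amount. The highest T cell identity value had an SE of 0.09, and the cytotoxic list had an upper quartile of 1.40. These values argue against this cause for the cytotoxic genes above that list's median. For smaller rises it stays open. No biological explanation was tested.

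The lowest standard errors in the authors' deposited table belong to 10 genes, Xist and 9 genes of the Y chromosome, at 0.0762 to 0.0782, against 0.0906 for the next gene. The other 4 of 13 Y-linked genes in the authors' deposited table lie above them, at 0.0983 to 0.230. The 10 genes sit near 0.0765, the value expected where the fitted dispersion meets an upper limit of 10. Their fold changes lie near 0, as for Xist at −0.01 and Ddx3y at 0.00. These 10 genes, chosen after their values were seen, suggest that libraries within a group differ in the sex of their cells, in which case they are not technical repeats of 1 pool. An even mix of both sexes in every library is argued against by 4 of them, whose standard errors lie below counting noise at means where at most 0.106% of other genes do. Near-zero fold changes of these genes then say nothing about expression, and any effect of sex on other genes was not tested.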
